A study of Mus musculus with 6 samples.

How the data were processed

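RNA sequencing was done on primary CD8+ T cells from mouse spleen that had been treated for 2 h with daunorubicin (DNR), an anthracycline that intercalates into DNA and poisons topoisomerase II, or with the solvent dimethyl sulfoxide (DMSO) as the control. The 6 samples form 2 groups of 3. The labels call the samples of a group biological replicates and do not say whether they came from separate mice. The p-values therefore set the group difference against the spread between these samples, which may not be the spread between mice. Per the labels' protocols, libraries were made from total RNA with a SMARTER mRNA kit.

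The deposited table holds log2(FPKM + 1), which is fragments per kilobase of transcript, scaled to sequencing depth, on a log2 scale, for 1037 transcripts named by RefSeq accession. Its column names say FPKM, and the scale was read from the values: raising 2 to each value and subtracting 1 gave a number of 2 decimals in 100% of cells, within 1e-06 FPKM. Per the submitters' processing notes the genome builds were GRCm38 and mm10. The aligner, the quantification program, the annotation release and the rule by which transcripts entered the table are not given in the sources used here. The table's name calls it the matrix of a heatmap of DMSO against DNR, and 99.7% of the transcripts tested had groups that did not overlap, against 10% expected by chance for 3 against 3. The counts below therefore describe a list that had in all likelihood been chosen for a difference between these same samples, and they are not independent evidence that the groups differ or of how many transcripts changed in the cells.

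The 6 value columns carry codes that end like the sample descriptions. The codes with O and a number match the ending of the DMSO descriptions alone. The codes with D could begin either treatment's name and were given to DNR because each DMSO description already had its column. Every direction below rests on this reading of the column names, which was made from the names alone. All 6 columns were mapped to a sample.

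Transcript accessions were matched without their version to the RefSeq gene table of GRCm38.p6, which gave a gene for 1013 of the 1037 transcripts and 847 distinct genes. The other 24 transcripts have no symbol here. Coordinates are those of the gene in that table, 1-based. Of the 1037 transcripts, 646 carry accessions of computationally predicted models, and 137 genes have more than 1 listed transcript. Estimates for transcripts of 1 gene share reads, so a value of 0 can be a failed estimate. Transcripts with 0 throughout a group are described as listed at 0, with the value of each sample and no fold change. The 4 identical entries of Jund and a pair of identical entries of Egr2 are counted as transcripts in the test and as single genes in counts of genes.

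A transcript was tested if it reached 1 FPKM in at least 3 of the 6 samples, which kept 388 transcripts of 338 named genes. The deposited log2(FPKM + 1) values were compared as they are, without rescaling, with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the treatment alone. The design had assumed FPKM on a linear scale, and the deposited scale equals its planned log2 with a pseudocount of 1. A change is the DNR mean minus the DMSO mean on the log2(FPKM + 1) scale, which understates the change of low transcripts. Read counts were not used here, so the depth of each sample is unknown and no counting interval is given. Across the tested transcripts, samples of 1 group correlated at 0.989 to 0.993 and samples of different groups at 0.897 to 0.907.

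On simulated data with the means and residual spread of the 388 transcripts, 200 of them changed and 20 runs, the test recovered 47.7% of changes of 0.25 on the log2 scale, 77.0% of changes of 0.5 and 95.1% of changes of 1, and 2.55% of its calls were false. The spread came from transcripts probably chosen for a difference, and the simulation had no such choice. These shares may therefore be too favourable and do not give the error rate of the calls below.

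The gene lists, the design and the rule for naming genes were fixed before the data were examined. By that rule the text names the 12 transcripts with the largest change in each direction among those with a gene symbol, past the threshold and with groups that do not overlap (symbols of predicted genes and pseudogenes were passed over), up to 4 transcripts per gene list with the smallest adjusted p where a list has at least 2 tested, and Mdm2 and Jun from a set of fixed genes. A further 10 transcripts in each direction, chosen the same way among transcripts above 0 in all 6 samples, were added after the values were seen, as were genes named as such. Transcripts without a matched symbol, 11 of those past the threshold, were passed over in both choices; 1 fall and 1 rise among them were larger than the smallest of the 12, and 4 rises and 0 falls larger than the smallest of the 10. Some of the transcripts these rules select are not reported here. Since 387 of the 388 tested transcripts had an unadjusted p under 0.05, every list member among them, adjustment over a list alone could not end a call here and adds no evidence. Of the 28 gene lists, 17 had a tested transcript and 2 had at least 5, the minimum for limma's camera test, which was run with a preset correlation of 0.01 between genes and compares a list with the other tested transcripts of the table.

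Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, shifting the samples to a common median, quantile normalization, no mean-variance trend, the replicate number as a block, leaving out each sample, and for the lists an estimated correlation and fry. Added after the data were seen were identical transcripts counted once, only transcripts above 0 in all 6 samples, and listed transcripts summed per gene. Count models were planned for a table of counts only and were not run. For the closing section, gene spans came from the RefSeq table and the longest transcript of each gene from GENCODE M21, which is also on GRCm38.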

Results

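The comparison asked which transcripts differ between CD8+ T cells exposed to daunorubicin (DNR) for 2 h and cells given the solvent DMSO, in a study on the effect of the drug on T cell activation. The table lists 1037 transcripts in 3 DMSO and 3 DNR samples. Between 583 and 594 of them were above 0 in each sample. Their FPKM summed to between 13501 and 13669 in the DMSO samples and between 14023 and 14395 in the DNR samples. A total of 347 transcripts were above 0 in all 6 samples, and 326 were above 0 in only 1. Depth is unknown, since FPKM keep no read totals. All directions rest on the reading of the column codes given with the processing.

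Of the 388 transcripts with enough signal to test, 167 were higher and 220 were lower in DNR, and 1 did not pass the threshold (limma, threshold 0.05 on the adjusted p). The one that did not pass was a transcript of Mdn1, at 14.3 ± 0.20 FPKM in DMSO and 12.9 ± 0.40 in DNR. The higher transcripts belong to 158 named genes and the lower ones to 199. Most changes were small. Among transcripts above 0 in all 6 samples, the median change was 0.43 for the 137 that rose and -0.41 for the 194 that fell. Of these, 19 that rose and 18 that fell changed by at least 1 on the log2(FPKM + 1) scale. That scale understates the change of low transcripts, so more may have changed by 2 times in FPKM. Abundant transcripts moved least: at a mean of 20 FPKM or more, the median change was 0.25 for 67 that rose and -0.24 for 59 that fell. The highest transcript in the table, Actb, which encodes beta-actin, rose from 1042 ± 19.5 to 1136 ± 36.7 FPKM (SD, n = 3), a difference that quantile normalization sets to 0 because Actb ranks first in every sample. Since the list appears to have been selected for a difference, the number of calls says little of the whole transcriptome. The same holds for the smaller changes of abundant transcripts, as low and variable ones would enter such a list only with large changes. The split between directions depended on scaling. As deposited, 43.2% of calls were higher and 56.8% lower. With the samples shifted to a common median, which moves DNR up by 0.18 against DMSO, 61.2% were higher and 38.8% lower. With quantile normalization 46.6% were higher and 53.4% lower. Both scalings were estimated on this list alone, in which more transcripts fell than rose, so they can remove a true imbalance. No library-wide scaling could be made. A call lost under them below shows dependence on scaling and not which scaling is right.

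**Figure D1:**
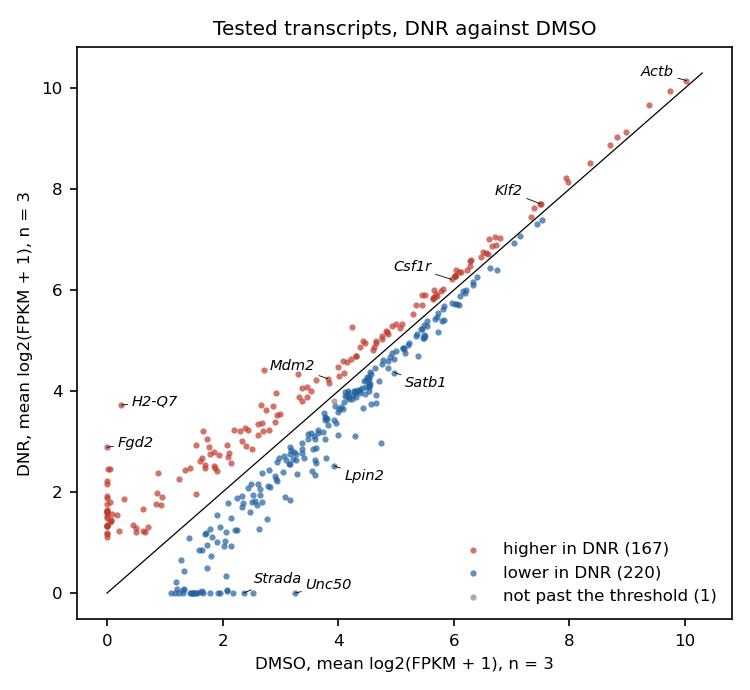
Mean log2(FPKM + 1) of each tested transcript in DMSO (x axis) and DNR (y axis), 3 samples per group, with the line of equal values. The 167 higher and 220 lower transcripts lie on either side of the line, close to it at high expression, and some transcripts lie at 0 on one axis, such as 1 of Unc50 and 1 of Strada.

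All 3 target genes of the DNA damage-responsive factor p53 that the table lists were higher in DNR, and 3 passed when adjusted over the list alone. The other genes fixed for this list, Cdkn1a and Bax among them, were not among the matched genes of the table. A change of p53 targets as a group can therefore not be read from it. Mdm2, which encodes the ubiquitin ligase that restrains p53 (chromosome 10, 117688875 to 117710758), rose from 13.2 ± 1.37 to 18.0 ± 1.82 FPKM (SD, n = 3), a log2 change of 0.43 ± 0.10 (SE; limma, adjusted p = 0.0061). Plk3, a stress-responsive kinase (chromosome 4, 117128655 to 117133963), rose from 31.0 ± 1.56 to 39.0 ± 1.89 FPKM. Pmaip1, which encodes the pro-apoptotic protein Noxa (chromosome 18, 66458604 to 66465558), rose from 53.9 ± 0.058 to 62.0 ± 0.97 FPKM. Their adjusted p-values by limma were 0.0026 and 0.0017. The list had too few tested genes for a list test, and its members were tested on a table that appears to have been chosen on these samples. Plk3 and Pmaip1 span under 10 kb, and of the genes under 10 kb with calls in 1 direction, 43 rose and 4 fell. Csf1r, a macrophage marker discussed with the cell type markers, rose by a similar amount.

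The few immediate-early genes in the table, a class that responds within minutes to receptor or stress signals, moved mostly up. The other genes fixed for this list of immediate-early and T cell activation genes, such as Fos, Egr1, Myc and Cd69, were not among the matched genes. A change of the whole class can therefore not be read from the table. Of the 7 tested genes of this list, 6 rose and 1 fell, and 11 of their 11 transcripts passed when adjusted over the list alone. Jun (chromosome 4, 95049036 to 95052222), a component of the AP-1 factor, rose from 49.4 ± 1.53 to 63.0 ± 5.70 FPKM (SD, n = 3; log2 change 0.34 ± 0.07; limma, adjusted p = 0.0037). The orphan nuclear receptor gene Nr4a2 (chromosome 2, 57106830 to 57124003) rose from 26.0 ± 1.61 to 33.0 ± 1.92 FPKM and Ier5 (chromosome 1, 155096367 to 155099636) from 78.0 ± 2.05 to 96.4 ± 5.95 FPKM. Atf3, a stress-induced transcription factor gene, rose from 67.5 ± 4.15 to 81.3 ± 3.98 FPKM. Jund and Ier2 rose by 0.27 and 0.20 on the log2 scale, the latter not past the threshold with quantile normalization (limma, adjusted p = 0.85). Egr2, induced by T cell receptor signals, went the other way, from 33.7 ± 2.03 to 28.0 ± 1.53 FPKM, and did not pass with samples shifted to a common median (limma, adjusted p = 0.43). The list was higher relative to the other tested transcripts (camera, adjusted p = 0.042 over 2 lists; 0.0078 to 0.068 when a sample was left out), but the call was lost with an estimated correlation (adjusted p = 0.63 with an estimated correlation) and with the identical Jund and Egr2 entries counted once (adjusted p = 0.069). The 7 genes span 1.5 to 17.2 kb, while the genes that fell had a median span of 71.2 kb. The camera test therefore cannot tell a rise of this list from the rise of short genes described in the closing section. Csf1r rose by 0.25 in the same samples, within the range of the genes of this list.

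**Figure D2:**
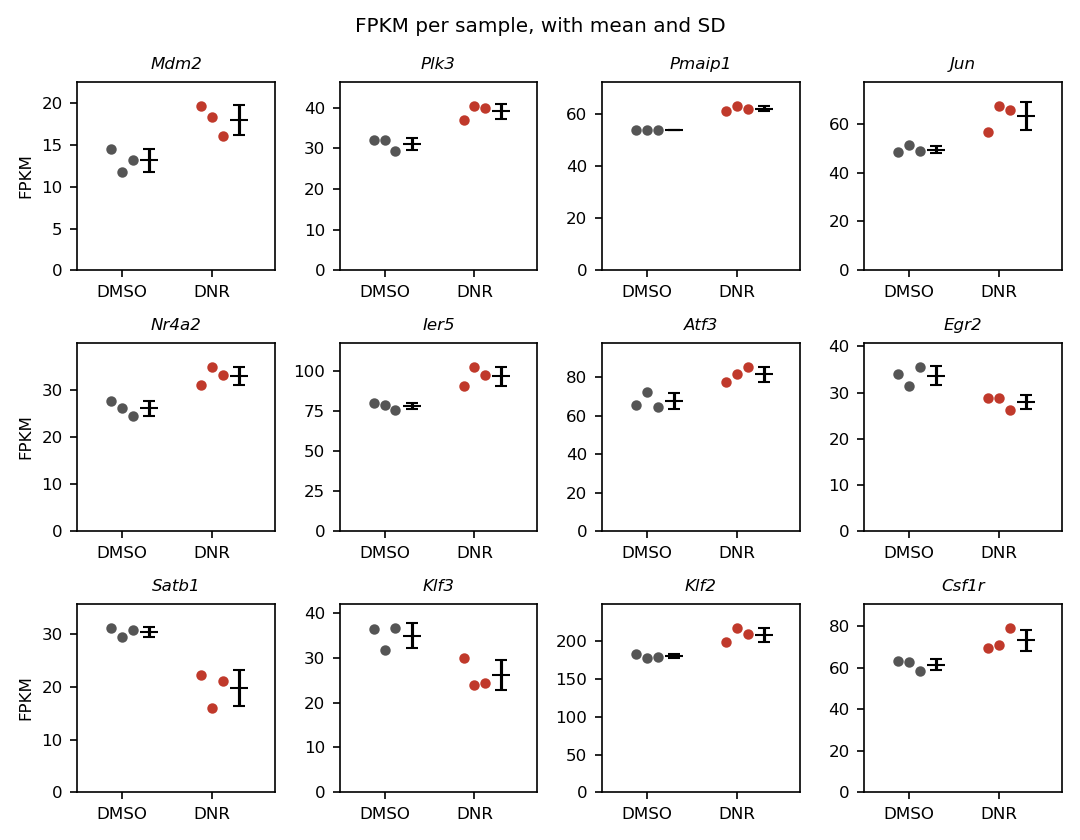
FPKM per sample (points) for 12 transcripts in DMSO and DNR, with the mean and SD of each group of 3 (bars); every y axis starts at 0. Mdm2, Plk3, Pmaip1, Jun, Nr4a2, Ier5, Atf3, Klf2 and Csf1r are higher in all 3 DNR samples than in any DMSO sample, and Egr2, Satb1 and Klf3 are lower.

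Genes of naive and memory T cells went in both directions. Of the 6 tested transcripts of 4 genes, 2 rose and 4 fell, and all 6 passed when adjusted over the list alone. Satb1, a chromatin organiser of T cells (chromosome 17, 51736187 to 51833290), fell in both tested transcripts, the lower one from 30.4 ± 0.92 to 19.8 ± 3.34 FPKM (SD, n = 3; log2 change -0.61 ± 0.12; limma, adjusted p = 0.0034) and the more abundant one from 79.8 ± 4.27 to 70.2 ± 2.13 FPKM. Klf3 fell from 34.9 ± 2.75 to 26.1 ± 3.32 FPKM. Klf2, a factor that maintains T cell quiescence (chromosome 8, 72319062 to 72321654), rose from 180.1 ± 2.46 to 208.4 ± 9.13 FPKM. The list as a whole did not stand apart from the other tested transcripts (camera, adjusted p = 0.61; adjusted p = 0.63 with an estimated correlation). Klf2 differed by 0.01 with quantile normalization (limma, adjusted p = 0.72), and with samples shifted to a common median Klf3 and the abundant Satb1 transcript did not pass (limma, adjusted p = 0.075 and 0.96). Among the untested transcripts of this list, 1 of Bach2 stood at 0.71, 1.00 and 1.12 FPKM in DMSO and 0.32, 0.30 and 0.20 in DNR.

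The other lists had 3 or fewer tested transcripts. Of 3 cell cycle genes, Ccnd3, the gene of cyclin D3, rose from 21.2 ± 0.90 to 29.9 ± 2.89 FPKM and Rrm2, a subunit of ribonucleotide reductase, from 42.9 ± 0.49 to 51.6 ± 3.44 FPKM (SD, n = 3), while 1 transcript of Ccne2 was at 2.30, 2.86 and 1.45 FPKM in DMSO and listed at 0 in all 3 DNR samples. Of the 2 NF-kB genes, Nfkbid rose from 65.3 ± 5.97 to 83.8 ± 3.04 FPKM and Birc3, which also stands in the apoptosis list beside Pmaip1, fell from 21.3 ± 0.23 to 17.6 ± 0.38 FPKM. Of the 2 lipid genes, Hmgcs1, of cholesterol synthesis, rose from 15.0 ± 1.94 to 21.2 ± 1.39 FPKM and the cholesterol exporter gene Abca1 fell from 18.2 ± 1.82 to 14.1 ± 0.73 FPKM. The falls of Birc3 and Abca1 did not pass when the samples were shifted to a common median (limma, adjusted p = 0.28 and 0.16) or with quantile normalization (limma, adjusted p = 0.15 and 0.10). Of 8 lists with 1 tested transcript, not counting the cell type markers, a transcript rose in the lists for DNA damage (Usp1), oxidative phosphorylation (Ndufs1), heat shock (Hspa8) and oxidative stress (Gpx1). In the glycolysis and hypoxia list, 1 transcript of Vegfa was listed at 0 in the DMSO samples and at 1.77, 1.66 and 1.27 FPKM in the DNR samples. A transcript fell in the lists for T cell receptor signalling (Nfatc3), ribosome biogenesis (Heatr1) and the unfolded protein response (Edem1). Each list had 1 pass when adjusted over the list alone, but Nfatc3 and Heatr1 did not pass with samples shifted to a common median (limma, adjusted p = 0.34 and 1.00), nor Heatr1 and Hspa8 with quantile normalization (limma, adjusted p = 0.15 and 1.00). The lists for effector cytokines and cytotoxic granules, inhibitory receptors, interferon-stimulated genes, histones, topoisomerases, ribosomal proteins and mitochondrially encoded genes had 0 tested transcripts.

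Members of the fixed marker lists of other cell types were few in the table, and 1 of them was abundant. Il1b and Tgfbi, which are outside these lists, are described with the closing observations. Csf1r, the receptor that marks monocytes and macrophages, stood at 61.5 ± 2.64 FPKM in DMSO and 73.3 ± 5.12 FPKM in DNR (SD, n = 3; log2 change 0.25 ± 0.06; limma, adjusted p = 0.0057), which is above the level of Jun or Nr4a2. In the dendritic cell list, 1 transcript of Itgax was listed at 0 in DMSO and at 1.51, 1.20 and 1.14 FPKM in DNR, while another was at 1.23, 0.96 and 1.19 FPKM in DMSO and listed at 0 in DNR. The B cell list had 3 listed transcripts, of Spib and Ebf1, all untested. The lists for natural killer cells, CD4 T cells, and erythroid cells and platelets had 0 listed transcripts.

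The largest differences were transcripts seen in 1 group alone or nearly so. Among the 12 largest falls of transcripts with a matched gene symbol, XM_006496223 of Unc50 was at 8.75, 5.75 and 12.22 FPKM in the DMSO samples and listed at 0 in the DNR samples. NM_011386 of Skil, the gene of the Smad inhibitor SnoN (chromosome 3, 31095058 to 31122923), was at 3.26, 3.44 and 4 FPKM in DMSO and at 0.01, 0 and 0 in DNR. Transcripts of Strada (4.46, 4.14 and 3.85 FPKM in DMSO), Chm (1.46, 3.19 and 4.74) and Cyrib (2.04, 1.79 and 3.72) were listed at 0 in every DNR sample, as was that of Ccne2. Those of Abcb6, Cacna1i, Ggta1 and Tmem19 reached at most 0.13 FPKM there. Among the 12 largest rises of transcripts with a symbol, transcripts of Dgkz, Drg2, Fcna, Fgd2, Ly6e, Sft2d1, Tmem19 and Tsc22d3 were listed at 0 in every DMSO sample. In the DNR samples, the FPKM were 6.71, 3.26 and 11.34 for Fgd2, 5.34, 2.6 and 3.37 for Dgkz and 3.02, 7.92 and 1.51 for Ly6e. They were 4.39, 1.96 and 2.36 for Fcna, 4.83, 1.34 and 2.62 for Drg2, 2.27, 1.56 and 3.65 for Sft2d1 and 2.89, 2.10 and 1.45 for Tmem19. The Tsc22d3 transcript, of the gene that encodes the glucocorticoid-induced protein GILZ, was at 2.61, 1.99 and 1.89 FPKM in DNR. Mindy3, Ppfia1 and Stx16 reached at most 0.12 FPKM in DMSO. An entry of the MHC class I gene H2-Q7 was at 0.07, 0 and 0.57 FPKM in DMSO and 9.50, 10.63 and 17.86 in DNR, and it is uncertain because genes of this family share near-identical sequence. Among transcripts with no symbol, 1 fall and 1 rise were larger than the smallest of these: the former was at 2.69, 7.03 and 5.35 FPKM in DMSO and listed at 0 in DNR, and the latter was above 0 in all 6 samples. In all, 19 tested transcripts that rose and 17 that fell were at 0 throughout a group.

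Transcripts above 0 in all 6 samples give the changes that can be expressed as a size. The largest rise among them, 1.71 on the log2 scale, was of a transcript with no matched symbol, from 2.37, 11.03 and 5.92 FPKM in the DMSO samples to 19.82, 22.93 and 18.60 in the DNR samples. The transcripts described next have a symbol. Each value is of 1 listed transcript and not of the whole gene, whose unlisted transcripts could offset it. Lpin2, which encodes a phosphatidate phosphatase (chromosome 17, 71183532 to 71249818), fell from 14.2 ± 0.97 to 4.86 ± 1.44 FPKM (SD, n = 3; log2 change -1.41 ± 0.19; limma, adjusted p = 0.00093). Ints13, of the Integrator complex, fell from 8.10 ± 1.91 to 2.66 ± 0.93 FPKM, and the reticulophagy receptor gene Retreg1 from 18.7 ± 1.45 to 8.29 ± 4.27 FPKM. Transcripts of Cdk17, Dennd4a, Papss1, Fnbp1 and Ciz1 fell by 1.30, 1.28, 1.18, 1.22 and 1.24 on the log2 scale. Among those that rose, Cd300lf, a myeloid inhibitory receptor gene (chromosome 11, 115116214 to 115135372), went from 2.41 ± 0.15 to 6.38 ± 0.22 FPKM (log2 change 1.11 ± 0.10; limma, adjusted p = 0.00019). A transcript of Ikzf1, a lymphoid transcription factor gene, went from 1.56 ± 0.31 to 4.42 ± 0.75 FPKM, and 1 of Raly from 6.77 ± 1.81 to 14.7 ± 2.09 FPKM. A transcript of Mrpl10 went from 0.89 ± 0.51 to 4.25 ± 1.07 FPKM. Transcripts of Cdk12, Ndufs1, Ythdc1, Baz2a, Strada and Mbnl3 rose by 1.54, 1.11, 1.05, 1.04, 1.04 and 1.03 on the log2 scale.

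For 20 genes, called transcripts of the same gene went in opposite directions. For Unc50, NM_001356528 rose from 8.99 ± 1.24 to 19.2 ± 1.79 FPKM (SD, n = 3) while XM_006496223 was listed at 0 in DNR, and the sum of the listed transcripts was 17.9 ± 4.36 FPKM in DMSO and 19.2 ± 1.79 in DNR (limma on gene sums, adjusted p = 0.52). For Fgd2, the sum was 12.8 ± 0.43 FPKM in DMSO and 12.7 ± 1.95 in DNR (adjusted p = 0.87 by limma). Of the 20 gene sums, 2 rose (Mindy3 and Psap), 2 fell (Cdk12 and Tmem19) and 16 did not pass the threshold. The sums cover listed transcripts only.

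**Figure D3:**
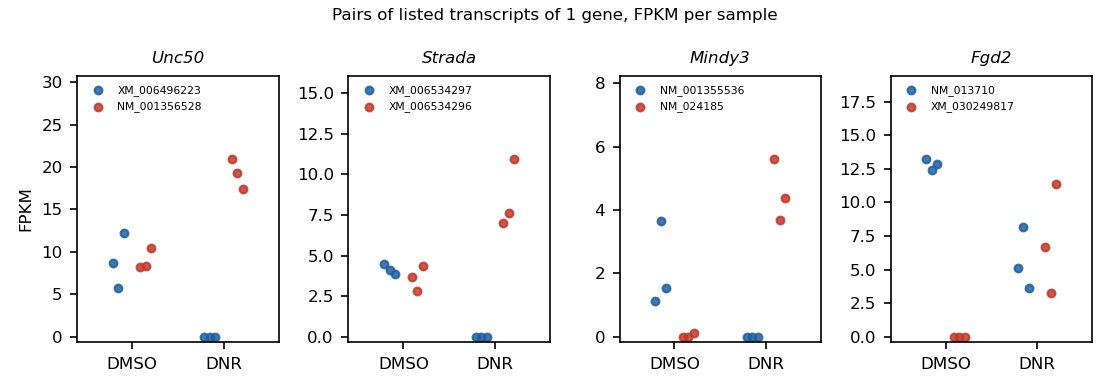
FPKM per sample of a pair of listed transcripts of Unc50, Strada, Mindy3 and Fgd2 (colours name the accessions) in 3 DMSO and 3 DNR samples. In each gene 1 transcript is lower and the other higher in every DNR sample.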

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

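The test of transcript pairs was chosen after the result was seen, and that of low values before. Outside the tested set, 94 transcripts below the filter were at 0 in all 3 DMSO samples and above 0 in all 3 DNR samples, which set them apart because the controls list them at 0, with a highest DNR mean of 2.69 FPKM. In the opposite direction, 105 untested transcripts were at 0 in DNR and above 0 in every DMSO sample.

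With the tested ones, 235 transcripts were at 0 throughout a group and above 0 throughout the other. Their median level where present was 0.78 FPKM, against 13.4 FPKM for transcripts above 0 in all 6 samples, which is what values near the detection limit would give. Of 40 genes with such a transcript and another listed one, 82.5% had a transcript going the other way, against a mean of 55.5% when directions were shuffled (one-sided, permutation p = 0.0005 over 10000 shuffles). The opposite directions are consistent with reads being assigned to different transcripts of a gene, while the low levels bear only on detection and would also follow from weakly expressed genes switching on or off. A change of promoter or splicing under DNR would also give opposite transcripts and stays open, as reads over junctions were not analysed here.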

How the results depend on the processing

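Of 876 alternative values for the 58 named transcripts, 870 kept direction and side of the threshold, 6 kept direction but lost the call (Abca1 and Birc3 with samples shifted to the same median and with quantile normalization, Klf3 with the former, Klf2 with the latter) and 0 reversed. Leaving out a sample ended no named call in 348 values. Most named transcripts were chosen for large changes or small p-values in these same samples, so their stability was partly fixed in advance. Genes named outside these 58 are not counted here, and some lost the call or turned under the scalings. Over all tested transcripts, samples shifted to a common median kept 273 of 387 calls, and 19 changes turned sign. Quantile normalization kept 320 and turned 11, and leaving out a sample kept 376 to 383. Called transcripts with a change of at least 2 times are those of 1 or more on the log2 scale with the pseudocount used. Their number, 93, became 155 with no filter and 20 with the stricter filter. It became 37 among transcripts above 0 in all 6 samples and 59 as listed transcripts summed per gene. Fewer or more transcripts tested (1037, 265, 332 and 350 against 388) is part of that. Pseudocounts of 0.5 and 0.1 gave 107 and 124. Higher transcripts became 111 with the stricter filter, which tests fewer. Lower transcripts became 106 when samples were shifted to the same median, which raises DNR by 0.18 against DMSO. Other counts stayed within 1.5 times. For the immediate-early list the camera adjusted p was 0.052 with pseudocount 0.1, 0.053 with quantile normalization, 0.069 with identical transcripts counted once and 0.63 with an estimated correlation, 0.0078 without DNR replicate 1, 0.052 and 0.057 without DMSO replicate 2 or 3 and 0.067 and 0.068 without DNR replicate 2 or 3. The cause was not tested. For the naive and memory list fry gave 0.029, since it asks whether the genes move one way on balance and not whether they stand apart. With the replicate block 385 transcripts passed; the numbers did not pair the samples (correlations of same-numbered deviations -0.05, 0.05 and 0.04), and not every sample correlated best with its own number. The real split gave 387 transcripts and the highest of the other 9 splits 0, with 1 of 10 splits as large as the real one, which is too few splits for a share under 0.05, on a table that appears chosen for this split. Depth limits what can be said of transcripts under 1 FPKM.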

Other observations

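The test of gene span itself, the limits for reading it, its repeats under other scalings and the test of myeloid transcripts were chosen after the result was seen. Other genes that changed are named here after their values were seen. Hexim1, which encodes an inhibitor of the elongation factor P-TEFb, rose from 27.4 ± 0.16 to 35.3 ± 0.86 FPKM (SD, n = 3; limma, adjusted p = 0.00041), and the histone variant gene H3f3b rose from 664.8 ± 17.6 to 811.4 ± 43.7 FPKM, a difference that is 0 with quantile normalization. The genes Fli1 and Smad3 fell from 55.0 ± 4.87 to 40.7 ± 1.41 and from 22.1 ± 2.49 to 15.1 ± 2.17 FPKM. The kinase gene Tec fell from 24.1 ± 0.79 to 14.4 ± 2.66 FPKM.

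The genes that fell were longer than the genes that rose. Among 317 genes with calls in 1 direction, the median genomic span was 71.2 kb for the 179 that fell and 17.7 kb for the 138 that rose. Genes over 100 kb numbered 53 among those that fell and 9 among those that rose, and genes under 10 kb numbered 4 and 43. Macf1 (338.2 kb), Arid1b (353.4 kb), Usp34 (187.4 kb) and Lyst (188.5 kb), all chosen after their values were seen, fell by 0.33, 0.20, 0.34 and 0.14 on the log2 scale, but none of the 4 passed with samples shifted to a common median (limma, adjusted p = 0.22, 0.87, 0.20 and 0.57), where Lyst turned to 0.04. Ier2, Klf2, Jund and Actb, all under 5 kb, rose, though with quantile normalization all but Jund differed by 0.01 or less.

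The difference in mean log10 span, fell minus rose, was 0.54 (permutation p = 1e-05, the smallest that 100000 permutations can give, as for the tests of span that follow). It was 0.49 within 5 bins of mean expression and 0.59 among transcripts above 0 in all 6 samples, and the change correlated with span across genes, which are not independent replicates (Spearman rho -0.35, Pearson r -0.31). With the calls made after samples were shifted to a common median (81 genes fell, 142 rose) the difference was 0.51, and with those after quantile normalization (137 and 123) it was 0.42. These values argue against expression level, values of 0 and a common FPKM scale as the whole cause. Within 5 bins of the longest annotated mRNA the difference was 0.25 (permutation p = 1e-05). Length still varies within a bin, and it is that of the gene's longest transcript, not of the listed one. The test therefore cannot exclude mRNA length, through RNA integrity or a length bias of the library, as the cause. Also, mRNA length differed between the genes that fell and those that rose (median 5694 against 3457.5 bp). Within 5 bins of span, its mean log10 still differed by 0.08 (permutation p = 0.0012). A candidate explanation, not tested here, is that 2 h of a DNA-intercalating topoisomerase poison lowers the output of long transcription units relative to short ones. The pattern was found on a table that had probably been chosen for a difference and that has no list of unchanged genes to set it against. The largest adjusted p over the 7 permutation tests of span was 1e-05.

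Of the 3 listed transcripts of the myeloid marker list, that of Csf1r was at 58.5 to 79.1 FPKM over the 6 samples, and those of Csf3r and Cybb did not reach 1 FPKM in all 6 samples. Among genes named after their values were seen, Il1b, which encodes a cytokine of myeloid cells, rose from 44.6 ± 4.95 to 59.0 ± 5.58 FPKM and Tgfbi from 23.5 ± 0.21 to 28.1 ± 1.19 FPKM (SD, n = 3), while Slfn4 fell from 12.8 ± 0.92 to 7.31 ± 0.82 FPKM. Cd300lf, the myeloid receptor gene named above, was at 2.41 ± 0.15 FPKM in DMSO and 6.38 ± 0.22 in DNR. The levels of Csf1r (lowest value 58.5 FPKM) and Il1b are what myeloid cells among the cells sequenced would give. Whether such cells were present was still not settled. The Csf1r level prompted the question and Il1b was picked after its values were seen, so neither is a test of it. The other 2 listed markers were at 0 in 5 of 6 samples each. Those zeros are of 1 listed transcript per gene in a selected table, so they do not give the level of Csf3r or Cybb. While the question is open, the changes described above cannot be credited to CD8+ T cells alone. Abundant myeloid genes, such as Lyz2 and Cst3, were not analysed here, and the purification of the cells is not described beyond their label.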
